A study of Arabidopsis thaliana with 2 samples.

How the data were processed

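Total RNA from lateral roots of Arabidopsis thaliana Col-0, a standard laboratory accession, was labelled with biotin and hybridised to 2 one-colour oligonucleotide arrays of 22810 probe sets each. One array carried the control roots (Con), for which the labels record no nematode treatment. The other carried the infected roots (Inf), in which pieces of root holding syncytia, the feeding cells that a cyst nematode induces, had been cut out 21 days after infection. How the control roots were cut and stored is not given in the sources used here.

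The deposited values are intensity values on a linear scale, 1 per probe set. The submitters' processing notes name MAS5, the array maker's algorithm that summarises the probes of a probe set into a signal; its version and settings are not given in the sources used here. In the deposited values both arrays had a 2% trimmed mean of 100.007, so they had been brought to one target before deposit. No detection calls were used here. Each group had 1 array, so the precision of every value is limited by that number, and no test, p-value or error between replicates can be given. Comparisons below describe these 2 arrays.

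From the deposited values, both arrays were set to the same 2% trimmed mean, which left them as they were. Signals at or under 35.1, the 40th percentile of all signals of both arrays together, were set to that floor, and values were taken to log2. The log2 ratio is Inf minus Con. A probe set at or under the floor on both arrays counted as not measured. Where 1 array was at the floor, the ratio is a bound, printed as "at least" or "or lower". List medians take such genes at their bound. Array controls (64 probe sets) stayed out of the counts. A probe set was counted as higher or lower at a ratio of 2-fold, and a second count used 4-fold.

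Genes were named through a table that pairs probe sets with an old platform annotation, updated by Entrez gene number through RefSeq gene names of the assembly TAIR10.1, which was used for names and for the chromosome of plastid genes only. The table listed 14016 probe sets, of which 13513 had 1 gene and 503 had several; the other 8794 are unnamed here, which does not mean that they have no gene. Of the 1-gene probe sets, 13436 matched a RefSeq gene. Most of the listed genes carry a locus code as their symbol (11933 probe sets), and many well-known genes are among the unnamed probe sets. No probe set with several genes was used for a named gene. Where a gene had several probe sets, the brightest by mean signal was taken. In 63 genes with more than 1 measured probe set, the log2 ratios of a gene's probe sets had a pooled SD of 0.38, and in 3 genes they lay more than 1 apart. This SD is the only measure of spread available for single genes, and it holds no biological variation.

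Before the data were examined, 51 gene lists (pathways, gene families and cell type markers) were fixed, with their matching rule. Of their members, 472 matched by locus and symbol and 11 were left out because the reference does not give that symbol to the locus. For each list with at least 3 measured genes, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins. The percentile describes the list on these arrays and is no test of infection. A list is called set apart when its percentile is at or under 2.5 or at or above 97.5. Because the annotation named few members, 14 lists reached 3 measured genes, 22 had 1 or 2, and 15 had none. The lists with none covered inositol oxygenases, sucrose cleavage (AT1G62660, which was measured, was among the members left out), jasmonate, ethylene, auxin transport, cytokinin response regulators, nitrate, phosphate, root meristem, amino acid transporters and aquaporins, and the first versions of the pectate lyase, ribosomal protein and organelle-encoded lists.

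For that reason 11 more lists were written by locus code or gene symbol, after the planned lists had been run. Of their measured members, 14 were also in planned lists, so their values had already been computed. The ratios of all other genes come from the same computation, and planned results on some of the same processes had been seen. The choice of the added lists can therefore not be called blind to the data. Membership was written from general knowledge and was not checked against a published list, which bears on the core hypoxia and peroxidase results in particular, including which peroxidases are known from root hairs. The lists hold class III peroxidases, cytosolic ribosomal proteins, pectate lyases, histones (no member measured), cytosolic glycolysis, small heat shock proteins, core hypoxia-induced genes, proline-rich extensin-like proteins, common reference genes, plastid-encoded genes and mitochondrion-encoded genes. They are called added lists in the text.

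Genes to be named were chosen by a rule fixed before the data were examined. The rule takes the 12 highest and 12 lowest ratios among 1-gene probe sets above the floor on both arrays, with the same direction under every scaling tried. It adds the 4 brightest genes per direction whose other array was at or under the floor. For each list described it takes up to 3 members in the direction of the list and up to 1 against it. Any member of a planned list, the reference genes and the array controls could also be named.

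The counts, list medians and single genes were recomputed with values as deposited, with arrays set to the same median, by quantile normalization, by a lowess curve along signal (span 0.3), and by scaling to the bacterial and phage spike-in transcripts. They were also recomputed with the floor at the 20th or 60th percentile, with a pseudocount in place of the floor, with no floor, and without probe sets that can bind several transcripts. Lists were further recomputed with the mean over a gene's probe sets, with the mean of the list and with random lists not matched on signal. The counts without plastid-encoded genes, and the added lists without the members shared with planned lists, were added after seeing the data.

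The scripts were tested on simulated data made from the real mean signals, with a noise SD of 0.2 per array and 200 altered probe sets. The altered probe sets all had a mean signal well above the floor, and the noise was the same at every signal. The rates that follow check the scripts and are not error rates of the real arrays, whose noise between replicates is not known. Of the probe sets altered by 1.5 on the log2 scale, 98% of those raised and 96% of those lowered were called at 2-fold, against 0.05% of the unaltered ones. All those altered by 3 were called. Of 400 unaltered lists of 15 genes, 18 lay outside the percentiles, and 10 of 10 lists shifted by 0.5 did. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.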

Results

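The transcripts of lateral roots were measured on 2 arrays, 1 of control roots (Con) and 1 of roots infected with the beet cyst nematode Heterodera schachtii (Inf). Both arrays came from Arabidopsis Col-0 at growth stage 6.1, grown at 20.5 °C with 16 h of light and 8 h of dark. For the infected array, plants aged 21 days received 35 sterile infective juveniles on a small filter paper, which touched the elongation zone of 3 lateral roots per plant for 48 h. Root pieces with syncytia were collected 21 days after infection and the female nematode was taken off. For the control array the labels record no plant age and no contact with filter paper, so equal age cannot be assumed. The study's title places the comparison under plant gene expression that goes with susceptibility to nematodes. The design has no replicates, so a difference between the arrays holds infection, sampling and array differences together.

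Relative to the bulk of the transcripts, infected root pieces had at least 2-fold higher signals than control roots for 27 of 65 plastid-encoded genes, 11 of 23 genes of the core hypoxia response, 4 of 8 small heat shock proteins and 3 of 16 expansins. They had at least 2-fold lower signals for single genes such as the terpene synthase TPS-CIN and for 8 of 37 class III peroxidases. The list medians of extensin-like wall proteins and xyloglucan endotransglucosylases were below 0, with no member called at 2-fold. Of 14759 measured probe sets, 442 were at least 2-fold higher in Inf and 519 at least 2-fold lower; 65 were at least 4-fold higher and 39 at least 4-fold lower. The remaining 93.5% did not reach 2-fold, among them probe sets at the floor on 1 array, whose ratio is a bound and may be larger. The median log2 ratio was 0.03. Signals of the 12542 probe sets above the floor on both arrays had a Pearson r of 0.908 on the log2 scale, across probe sets, which are not independent replicates.

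The share of higher among these calls depended on the scaling. It was 46.0% in the main values, 36.2% with the arrays set to the same median (362 higher, 637 lower) and 35.7% with a lowess curve (389 higher, 701 lower). The 18 spike-in probe sets were all brighter on the Inf array, with a median log2 ratio of 0.73 (SD across probe sets 0.18). Scaling to them moved the median log2 ratio of all measured probe sets to -0.63 and gave 107 higher and 3464 lower probe sets. Higher and lower below are therefore relative to the bulk of the measured transcripts. With spike-in scaling every list median was lower, and of those above 0 only the medians of the plastid-encoded, core hypoxia and small heat shock protein lists stayed above 0. A median close to 0 also turned below 0 with the same-median scaling for actins and tubulins, starch metabolism and the added reference genes, with quantile normalization for the planned peroxidases, and with the lowess curve for endoglucanases.

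**Figure D1:**
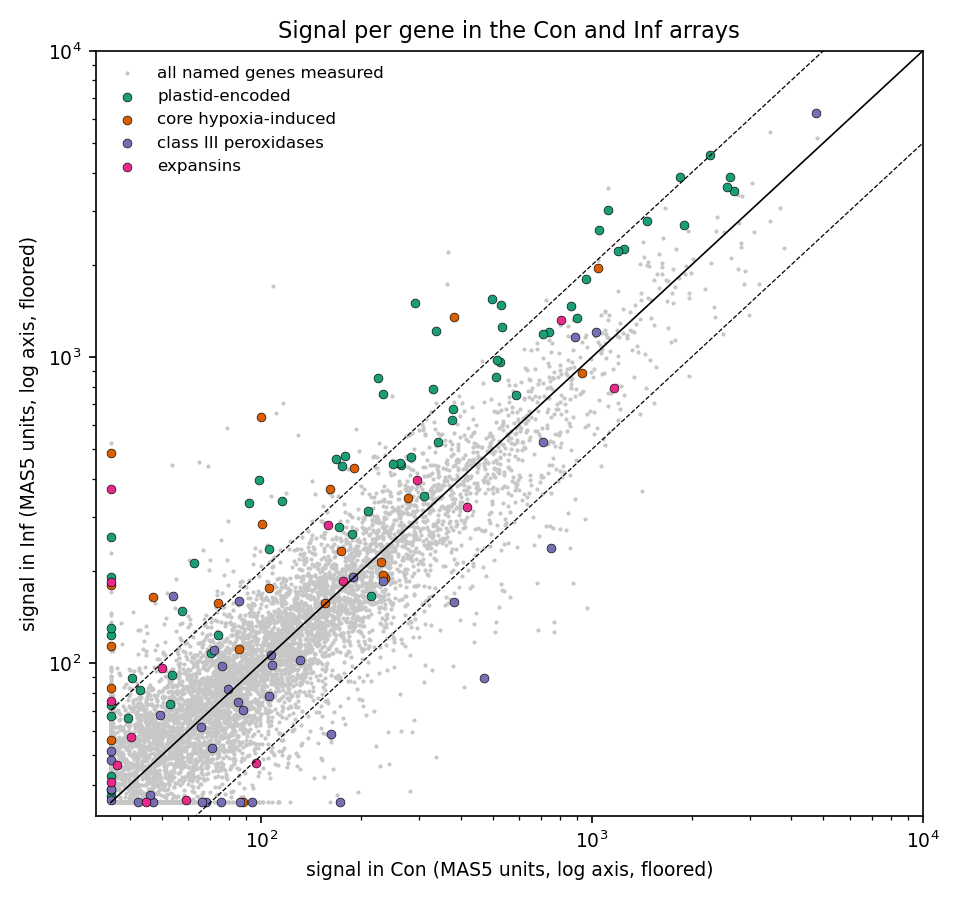
Signal of each measured gene on the Con array (x axis) and the Inf array (y axis), in MAS5 units on log axes, with values under 35.1 drawn at that floor. Each point is 1 gene, the solid line marks equal signal and the dashed lines mark 2-fold; most plastid-encoded genes and many core hypoxia-induced genes lie above the solid line and 23 of 37 class III peroxidases lie below it.

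The highest ratio above the floor on both arrays belonged to AT2G21130, a cyclophilin, with a signal of 108 in Con and 1706 in Inf (15.8-fold higher). Next were AT2G17280, of the phosphoglycerate mutase family, at 8.25-fold. Argininosuccinate synthase (AT4G24830), of arginine synthesis, was 7.47-fold higher, PANB2, of pantothenate synthesis, 6.98-fold, and the dihydroxyacid dehydratase AT3G23940, of branched-chain amino acid synthesis, 6.08-fold. The calmodulin-like gene AT1G18210 had 368 in Con and 2204 in Inf. AT4G39675, whose product has no stated function, was 6.37-fold higher, and LCR68, a defensin-like peptide, 4.75-fold (364 in Con, 1732 in Inf). The related defensin PDF2.1, listed beforehand as described in cyst nematode feeding sites, had 225 in Con and 417.5 in Inf, a log2 ratio of 0.89. GH9A3 (KOR3), an endoglucanase on the same prior list, had 42.3 in Con and 107 in Inf, a log2 ratio of 1.34. The other 12 members of that list with a match had no measured 1-gene probe set. LIL3:1, a light-harvesting-like protein, was at the floor in Con and at 525 in Inf.

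The lowest ratios belonged to genes of several functions. TPS-CIN, a cineole synthase, had 282 in Con and 38.2 in Inf, 7.39-fold lower, with the Inf signal close to the floor. UGT72E1, which glucosylates coniferyl aldehyde, was 5.18-fold lower, and AT3G13610, the hydroxylase that leads to the coumarin scopoletin, 5.16-fold lower, with its Inf signal of 37.9 close to the floor. The acyltransferase-family gene AT4G15390 was 5.35-fold lower. AT3G45710, of the nitrate and peptide transporter family, was 6.85-fold lower, the arsenate reductase AT2G21045 6.06-fold and the lipid-recognition protein AT2G16005 5.63-fold. The vacuolar invertase AT1G62660 had 876 in Con and 182 in Inf, 4.80-fold lower; it had been written for the planned list of sucrose cleavage but was left out for its symbol. AT2G44010, AT3G20015 (an aspartyl protease) and AT1G70880 (of the major latex protein-like family) were between 4.93-fold and 6.37-fold lower. Among genes at the floor in Inf, AT5G04120 was at least 4.59-fold lower, the alcohol dehydrogenase-family gene AT5G42250 at least 3.49-fold and AT3G25930 at least 3.22-fold. The genes with the highest and lowest ratios above the floor on both arrays were chosen for having the same direction under every scaling tried. For them the shared direction is part of the rule and not a result. The other genes in these paragraphs also kept their direction. The spike-in shift of 0.73 was too small to reverse any of them.

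Plastid-encoded genes stood apart as a group. Of 65 measured in an added list, 27 were at least 2-fold higher, none was at least 2-fold lower, and 64 had a ratio above 0. Their median log2 ratio was 0.89, at the 100th percentile of random lists, and 0.18 with spike-in scaling, which moves all ratios down. psbA, for the D1 protein of photosystem II, had 290.4 in Con and 1502 in Inf. ycf3 and ndhJ were at least 7.34-fold and 5.45-fold higher, with Con at the floor, and psaA had a log2 ratio of -0.37. The 9 measured nuclear members of the photosynthetic tissue list had a median log2 ratio of 0.07, among them LHCB4.1 with 1404.5 in Con and 1535 in Inf, and only LHCB4.3 reached 2-fold (log2 ratio 1.72). With its 4 plastid members that list had a median of 0.13 over 13 genes (80.4th percentile) and a mean of 0.55 (99.9th percentile). The 10 mitochondrion-encoded genes had a median of 0.21 (80.9th percentile), with 1 at least 2-fold higher. Without probe sets that can bind several transcripts, 7 mitochondrion-encoded genes had a median of 0.49 (99.2nd percentile). The control probe set for the 25S ribosomal RNA was 2.14-fold higher in Inf.

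Genes that most plant cells induce under low oxygen had a list median above 0. Of 23 measured genes of the added core hypoxia list, 11 were at least 2-fold higher, 1 was at least 2-fold lower and 11 were not called at 2-fold. Of the 23, 18 had a ratio above 0 and 5 below. The median log2 ratio was 0.90 (1.87-fold, 100th percentile), and 0.32 with spike-in scaling. AT4G33560 was at the floor in Con and at 485 in Inf, at least 13.8-fold higher, AT4G10270, of a wound-responsive family, had 99.4 in Con and 635 in Inf, and AT2G17850 was at least 5.12-fold higher. AT2G15880 was at least 2.51-fold lower. The planned list of hypoxia and fermentation had 1 measured member, HRA1, a regulator of the hypoxia response, at least 3.25-fold higher, and this gene is also 1 of the 23. Cytosolic glycolysis genes had a median of 0.34 over 9 measured genes (97.9th percentile), with none beyond 2-fold. The glycolysis list was no longer set apart in 10 of 14 alternatives, with a percentile as low as 86.0, and its median was -0.38 with spike-in scaling.

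Small heat shock proteins, chaperones that bind unfolded proteins, were higher as well. All 8 measured members of the added list had a ratio above 0 in the main values, and 4 were at least 2-fold higher. The median log2 ratio was 1.08 (100th percentile), and 0.54 with spike-in scaling. AT2G29500 had 129 in Con and 554 in Inf, AT1G53540 had 78.7 and 217, and AT5G51440 was at least 2.77-fold higher. AT5G48570 (ROF2), a heat-induced co-chaperone and the 1 measured member of the planned heat shock list, was 5.91-fold higher. The chaperones of the endoplasmic reticulum had a median of 0.20 over 3 genes (74.4th percentile).

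Cell wall families went different ways. Expansins, which loosen walls, were a planned list with 16 measured genes and a median log2 ratio of 0.39 (99.3rd percentile), 3 at least 2-fold higher and 1 at least 2-fold lower. EXPA16 and EXPA8 were at the floor in Con and at least 10.6-fold and 5.25-fold higher in Inf, EXLA2 was at least 2.14-fold higher, and EXPB1 was 2.04-fold lower. The expansin percentile was 96.6 with no floor and 96.5 with a pseudocount, and the median was -0.27 with spike-in scaling. Xyloglucan endotransglucosylases were all below 0, with a median of -0.46 over 6 genes (1.3rd percentile). None was called at 2-fold, but 2 of the ratios are bounds, among them that of XTH20, with 58.9 in Con and the floor in Inf. Their percentile was 7.86 with the higher floor. Proline-rich extensin-like proteins had a median of -0.52 over 9 genes (0.06th percentile), 8 of them below 0 and none called at 2-fold (2 are bounds), with HRGP1 at 381 in Con and 218 in Inf. Endoglucanases had a median of 0.10 over 10 genes (69.8th percentile), with GH9A3 the highest and GH9C1 at least 2.13-fold lower. Pectate lyases had -0.11 over 13 genes (12.0th percentile) and pectin methylesterases 0.30 over 3 (76.7th percentile).

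Class III peroxidases, enzymes of wall cross-linking and reactive oxygen, had a list median below 0. Of 37 measured genes in the added list, 8 were at least 2-fold lower, 1 was at least 2-fold higher and 28 were not called at 2-fold; 12 of the 37 ratios are bounds. The median log2 ratio was -0.27 (0.01st percentile), and the percentile was 3.27 with the floor at the 20th percentile and 3.17 with it at the 60th. AT4G30170 had 472 in Con and 89.2 in Inf, 5.30-fold lower, AT5G17820 was at least 4.92-fold lower, and AT2G37130 was 3.17-fold lower. AT5G06730 was higher, with 54.1 in Con and 166 in Inf. The 6 measured peroxidases of the planned list, which overlaps the added one, had a median of 0.14 (68.9th percentile). The brightest of them, PRXR1, had 4755 in Con and 6268 in Inf. The 4 measured peroxidases known from root hairs were all at the floor in Inf, with a median log2 ratio of -1.36 as an upper limit. Of the root hair expansins, EXPA18 had a log2 ratio of -0.73, and EXPA7, at the floor in Inf, -0.35 or lower.

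Transport and stress lists had medians on both sides of 0. Sugar transporters had a median of 0.35 over 13 measured genes (97.4th percentile, short of the limit), and all 13 were of the SWEET family of sugar exporters. The list was set apart in 7 of 13 alternatives, but its median was 0.10 with the floor at the 60th percentile (63.3rd percentile) and also 0.10 with the lowess curve. SWEET3 had 37.7 in Con, close to the floor, and 135 in Inf, and SWEET16, a vacuolar transporter, was 3.07-fold lower. The abscisic acid and dehydration list had a median of -0.43 over 4 genes (1.98th percentile), led by LTI30 with 2336 in Con and 1453 in Inf; it was not set apart in 6 of 13 alternatives. The wound, touch and elicitor list had -0.37 over 4 genes, 2 above 0 and 2 below (3.18th percentile), with WRKY6 2.42-fold lower. It was set apart in 5 of 13 alternatives, with a median of -0.80 with the lowess curve (1.3rd percentile), -1.48 with spike-in scaling and -0.75 with the floor at the 60th percentile (1.45th percentile), each over 3 genes. ZAT10, a rapid stress regulator, was bright on both arrays, with 1560.1 in Con and 928.5 in Inf. WRKY factors had a median of -0.09 over 6 genes (25.6th percentile).

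Lists of growth and general function had medians between -0.20 and 0.15. Cytosolic ribosomal proteins had a median of 0.15 over 118 genes (99.85th percentile), with 83 above 0 and 2 at least 2-fold higher, and -0.58 with spike-in scaling, where the bulk lay at -0.63. Actins and tubulins had a median of 0.03 over 8 genes (59.2nd percentile), 4 above 0 and 4 below. ACT11 had 60.3 in Con and 217 in Inf and TUB7 had 337 and 705, while the lowest log2 ratio of the list was -0.89. Core histones had -0.20 over 4 genes (20.4th percentile) and starch metabolism 0.06 over 3 (51.5th percentile). The 9 measured genes of the added reference list, which are used for their stable levels, had a median of 0.07 (67.3rd percentile), none beyond 2-fold and a range from -0.52 to 0.50. Of the planned reference genes, UBC21 had a log2 ratio of 0.10 and GAPC2 of 0.65.

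**Figure D2:**
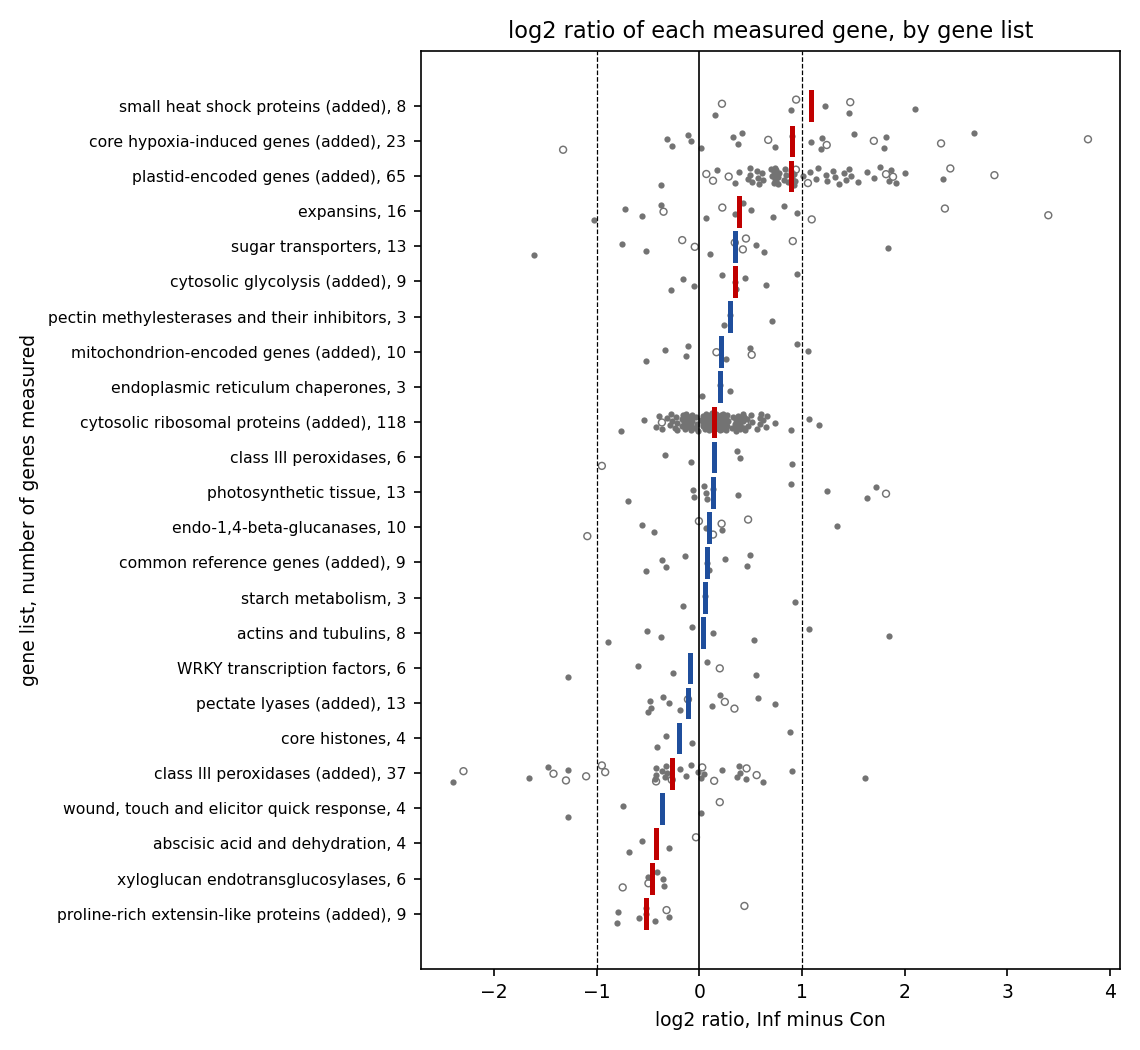
Log2 ratio (Inf minus Con, x axis) of each measured gene in each gene list with at least 3 measured genes (y axis, with the number measured). Filled points were above the floor on both arrays and open points are bounds; bars mark the list medians, red where the list was set apart from random lists and blue where it was not, with dashed lines at 2-fold. Small heat shock proteins, core hypoxia-induced genes and plastid-encoded genes have medians near 1.08, 0.90 and 0.89, and extensin-like proteins the lowest at -0.52; with spike-in scaling all medians are lower and those 3 alone stay above 0.

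The labelled RNA was compared at both ends of control transcripts. With the first probe design, the ratio of signal at the 3′ end over the 5′ end was 1.71 in Con and 1.81 in Inf for GAPDH, 2.28 and 2.398 for ubiquitin, and 4.90 and 3.48 for actin. With the second it was 1.02 and 1.03 for GAPDH, 1.68 and 1.43 for ubiquitin, and 1.59 and 1.32 for actin.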

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

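The tests in this part were chosen only after the result was seen. The control probe set for the 25S ribosomal RNA, which none of the comparisons uses, had a signal of 280.7 in Con and 600.0 in Inf, a log2 ratio of 1.096. It drew attention as a signal outside the main measurement that was higher than in the control.

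It bears on the plastid-encoded genes, whose transcripts, like ribosomal RNA, lack stable poly(A) tails. The tables argue against leaf or shoot tissue in the infected sample, over 9 measured of 54 nuclear photosynthetic genes. The plastid-encoded median lay 0.82 above theirs, over 2 times the SD of random lists (0.18). Abundant ones such as LHCB4.1 (1404.5 and 1535) and PSBW (1055 and 1092) hardly differed. Genes this bright in Con would show a small addition of tissue least. The comparison also takes such tissue to raise both sets by a similar ratio, which was not tested. LHCB4.3, 1 of the 9, was at least 2-fold higher. LIL3:1, outside that list, was at the floor in Con and at 525 in Inf. The tables also argue against a scaling that depends on signal, since the plastid-encoded median stayed 0.83 above that of all genes with quantile normalization and 0.90 above with the lowess curve. More label from RNA without poly(A) tails stays open. Mitochondrion-encoded genes lay 0.68 below the plastid-encoded ones, which speaks against it. They lay only 0.40 below without probe sets that can bind several transcripts. The 25S control (log2 ratio 1.096) went with this explanation, though all 18 spike-in probe sets were also higher, with a median of 0.73. The 5S ribosomal RNA control was under the floor on both arrays (17.3 in Con, 8.1 in Inf). A greater number or activity of plastids in infected roots may also be behind the plastid-encoded pattern and was not tested, with 1 array per group.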

How the results depend on the processing

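The tests in this part were planned except those for the 4-fold counts, the added lists, with or without members shared with planned lists, and the counts without plastid-encoded genes. With 1 array per group no replicate could be left out and no split of the samples is possible. No paired analysis was possible because each group has 1 array and no result comes from a test. Signal over background limits the dim end: 7987 probe sets at or under the floor on both arrays gave no ratio. Counts of probe sets 2-fold higher and lower, then 4-fold higher and lower, were 442, 519, 65 and 39 in the main values. They were 107, 3464, 25 and 218 with spike-in scaling, and 1300, 1109, 134 and 106 with the floor at the 20th percentile. With no floor they were 2504, 2282, 819 and 716, and with a pseudocount 278, 305, 40 and 14. With the floor at the 60th percentile they were 264, 343 and, for 4-fold lower, 18. The 4-fold higher count at that floor changed by a smaller ratio than these. The floor settings change by construction how many dim probe sets can reach 2-fold, and spike-in scaling shifts all ratios together. Without plastid-encoded genes 415 were 2-fold higher and 519 lower. Of the planned lists, 3 were set apart in the main values and 5 with the arrays set to the same median. Those that crossed the limits had been close to them. Sugar transporters went from the 97.4th to the 99.3rd percentile, and the wound, touch and elicitor list from 3.18 to 2.43. Why they moved was not tested. Of 320 recomputed list medians, 265 moved by less than the SD of random lists. These include 24 with values as deposited and 24 with random lists not matched on signal, where the median could not move. Of the 320, 24 changed sign, 13 of them with spike-in scaling. Of the 24 sign changes, 3 belong to lists set apart in the main values: expansins (-0.27), cytosolic ribosomal proteins (-0.58) and cytosolic glycolysis (-0.38), all with spike-in scaling. Core hypoxia-induced genes, plastid-encoded genes, small heat shock proteins, extensin-like proteins and ribosomal proteins stayed set apart on the same side in 14 of 14 alternatives, peroxidases in 12 of 14 and expansins in 11 of 13. The alternatives counted include the values as deposited, which equal the main values. They also include the same-median and spike-in scalings, which shift a list and its random lists together. With those scalings a percentile can change mainly through the floor, so they are weak checks of it. Without members shared with planned lists, 6 added lists were set apart in place of 7, since glycolysis had the 95.1st percentile. Of 1409 recomputed ratios of single genes, 1181 moved by less than the SD between probe sets of a gene. The other 228 moved by more, 135 of these with spike-in scaling. The 1181 include 144 with values as deposited and 141 without probe sets that can bind several transcripts, which could not move. None at 2-fold or beyond changed direction. For spike-in scaling this was fixed in advance, since its shift of 0.73 is too small to reverse a 2-fold ratio. It was also fixed for the same-median scaling, whose shift is smaller. The floor settings and the pseudocount keep the order of the Con and Inf signals, so they could not reverse a direction either. Only quantile normalization and the lowess curve could have done so. The genes named for the highest and lowest ratios had been chosen for keeping their direction under every scaling. For those genes the scalings could therefore show no change of direction.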

Other observations

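The tests of the hypoxia and peroxidase patterns in this part were chosen only after the result was seen. Several planned lists had only 1 or 2 measured genes, and these give values for processes not described above. Of the mitosis list, AUR2, an Aurora kinase, had 42.4 in Con and 129 in Inf, a log2 ratio of 1.60, while its relative AUR1 had 0.16. The replication helicase subunit MCM7 had -0.10. Of flavonoid synthesis, DFR, which leads to anthocyanins, had 314 in Con and 626.5 in Inf, and UF3GT had a log2 ratio of 0.57. HCT, of lignin precursor synthesis, had 0.37. UGT74B1 and BCAT4, of glucosinolate synthesis, had 0.49 and -0.26. For salicylic acid, GRX480 had -0.11 and SAG101, at the floor in Inf, -0.17 or lower. The Aux/IAA genes IAA18 and IAA30 had 0.11 and, with Con at the floor, at least 0.03, and the lateral root founding genes LBD16 and PUCHI had -0.27 and 0.29.

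Cell type markers were few. IRX10, of secondary walls, had a log2 ratio of 0.09, the phloem gene OPS at least 0.13 with Con at the floor, and the Casparian strip receptor GSO1 -0.57. COB, of cellulose synthesis, had -0.19, PYE, of iron homeostasis, 0.06, EIF4A-2 0.33, and the proteasome subunit RPN12a 0.03. The ribosome biogenesis genes PES and DIM1A had -0.59 and 0.03. With spike-in scaling these values move down with the bulk, to a median of -0.63 for all measured probe sets.

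Core hypoxia-induced genes had a median of 0.90. A scaling that depends on signal is argued against, since the hypoxia median stayed 0.78 above that of all genes with quantile normalization and 0.83 above with the lowess curve. Stronger wounding as the infected roots were cut out stays open: the wound, touch and elicitor list had a median of -0.37, but over 4 of its 18 genes, 2 above 0 and 2 below, and its member CML38 is also in the hypoxia list. The median was -0.80 with the lowess curve and -0.75 with the floor at the 60th percentile, farther from what wounding predicts, but over 3 genes, since WRKY53, 1 of those above 0, was then at or under the floor on both arrays. Low oxygen or altered metabolism in infected roots may account for the pattern, as a hypothesis that 1 array per group leaves untested, along with any difference in handling that the labels do not record.

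Class III peroxidases had a median of -0.27. A scaling that depends on signal is argued against as the whole of it, since the median stayed below that of all genes by 0.32 with quantile normalization, but the distance shrank from -0.31 in the main values to -0.18 with the lowess curve, where the list was at the 0.62nd percentile. Part of the difference thus depends on the scaling. A smaller share of root hair cells in the infected sample cannot be told apart from lower peroxidase transcripts. Without the peroxidases known from root hairs, the median of the other 33 was -0.13, at the 1.98th percentile of random lists but at 4.09 and 5.45 with the lowess and spike-in scalings. The 4 root hair peroxidases were all at the floor in Inf, so their median of -1.36 is an upper limit. An effect of infection on these genes stays open and untested.

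Because AT1G70880, AT4G23680 and AT1G14960 were seen among the lowest ratios, the rest of the major latex protein-like family was tested as a hypothesis, written before those values were looked at, that the family is lower as a whole. These 3 genes, chosen after their values were seen, were 4.93-fold, 3.87-fold and 3.86-fold lower. The other 7 measured members had a median of -0.30, at the 3.88th percentile of random lists, with 1 at least 2-fold lower, which is short of the limit set and leaves the hypothesis open.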
